A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

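The series holds 5 arrays of budding yeast RNA, each hybridised in 2 channels with material from the Yra1 and the Mex67 precipitate. The arrays form 1 group, were named replicates 1 to 5, and came in tables of 2 platforms, with replicate 1 in a table of its own. The titles of replicates 3 and 5 carry the same code, which was read here as a session, though the labels do not say what it means. No label says that the arrays came from separate cultures. P-values of tests over arrays then measure only the spread between these arrays, which may be technical. Those of camera also depend on the spread between genes, and permutation p-values on gene pairs within 1 array. The number of arrays limits the precision, and signal over background could not be assessed because only ratios were used here. The labels give no dyes and no dye swap, so a dye effect specific to a gene cannot be separated from a difference between the precipitates.

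The deposited values are log10 ratios per spot, which was worked out from the values because the scale is not given in the sources used here. Of 2000 spots drawn per array, 10 to the power of the value was a ratio of whole numbers up to 3000 (within 1.2e-09 log units) for 12.0, 3.90, 18.45, 3.65 and 2.35% on replicates 1 to 5, against at most 0.55% with base 2 and 0.9% with base e. The scanner, background correction and normalization are not given in the sources used here. The deposited ratios were not centred: the array medians were 0.32, 1.96, -2.81, -1.45 and -1.59 on the log2 scale for replicates 1 to 5. Which channel was the numerator stays unknown.

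The platform of 4 arrays has 12800 spots in 32 blocks of 20 by 20. In the outer 3 rows and columns of a block, neighbouring spots often held 1 identical deposited value. Such a value was taken here as a local value and not as the spot's own ratio. Of 6528 outer spots this share was 59.6% on replicate 2, 17.8% on replicate 3, 32.6% on replicate 4 and 76.9% on replicate 5, and among inner neighbours it was 0%. How these values arose is not given in the sources used here.

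Values were converted to log2, centred on the median of each array, and averaged over the spots of a gene. Genes were named through the platform annotation and updated through the RefSeq gene table of assembly R64, which matched 5534 of 5539 genes. On the platform of 4 arrays 11138 spots had 1 gene, 1662 none and 0 several. On the other platform 6695 of 7680 spots had 1 gene, 985 none and 0 several. Spots without a gene name were not used, 1 row whose ID was not a number was left out, and 2 IDs given on 2 rows were merged. No coordinates are given because the tables name no build.

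The main test, chosen before the data were examined together with the gene lists, the naming rule and most alternatives, was limma 3.58.1 (R 4.3.3): lmFit and eBayes of the 4 log2 ratios of a gene against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene needed values on at least 3 arrays. Of 29 lists, 26 with at least 5 measured genes were tested with camera against all other genes at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also takes its degrees of freedom from the arrays and not from the genes. With 4 arrays it is then a much weaker test, whatever the correlation between genes. The name pattern written for Ty retrotransposon reading frames matched no gene name, and the mitochondrial DNA and non-coding RNA lists had no measured gene, so these 3 lists were not analysed here. A list's shift is its median minus that of all other genes on an array, given as mean and SD over arrays. The tested lists share 11 genes.

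The text names, in each direction, the 12 genes of largest mean that passed, filled with genes of 1 sign on all 5 arrays where fewer passed (here all 12 on each side), YRA1 and MEX67, and from each list up to 4 members of smallest p, of which a part is printed. Genes chosen otherwise are said to be chosen after their values were seen. Correlations, gene length and permutations used Python 3.11.15 with scipy 1.17.1. Of the gene lengths 96.8% were multiples of 3, so the length of some genes may include introns.

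The fit was tested on simulated data made by shuffling genes within each array and adding known changes to 200 of 5539 genes. In 20 draws it recovered 0.9% of changes of 1 log2 unit, 43% of 2, 88.4% of 3 and 96.9% of 4, with a mean of 0.35 false calls, and 0 calls when nothing was added. Shifts of -0.3 in the ribosomal protein list and -1 in the glycolysis list were called in all 20 draws, with 0 lists called when nothing was added, in data where shuffling had removed the correlation between genes.

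Alternatives changed the centring, the scaling between arrays, the handling of the shared session, the platform added, the array weights, the summary of spots, the moderation and the version of camera, and left out each array in turn. Further ones were added after the data had been seen: removing the median of the 5 by 5 spots around each spot, leaving out outer spots with a shared value, turning the sign of replicate 2, and a session block. GC content and introns were not analysed here.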

Results

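RNA that co-precipitated with zz-tagged Yra1 was compared, on each 2-colour array, with RNA that co-precipitated with zz-tagged Mex67 from the budding yeast Saccharomyces cerevisiae. Mex67 is the principal export receptor for yeast mRNA, and Yra1 is an RNA-binding adaptor that acts with it in the nucleus. The comparison asks which transcripts were recovered unequally with these export proteins. Values are log2 ratios relative to each array's median. The labels place the Yra1 RNA in channel 1 and the Mex67 RNA in channel 2 on every array, but the sources used here do not say which channel was the numerator or which dye it carried. "Lower" and "higher" below therefore refer to the deposited ratio and do not name the precipitate that held more of a transcript. Replicates 2 to 5 shared 1 platform and were tested together, and replicate 1, on another platform, was set beside them.

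Of the 26 gene lists tested, 3 had lower ratios than other genes over the 4 arrays by limma's camera at a preset correlation of 0.01, and 0 lists passed with an estimated correlation. The 22 measured genes of glycolysis and fermentation lay -0.80 ± 0.38 log2 units from the other genes (SD, n = 4), a 1.75-fold difference of medians, and were lower on 4 of 4 arrays, but lay at -0.60 ± 0.73 with the sign of replicate 2 turned. The 132 cytosolic ribosomal protein genes lay at -0.42 ± 0.37, a 1.34-fold difference, lower on 4 of 4 arrays, and at -0.25 without replicate 5. The 40 translation factor genes lay at -0.29 ± 0.26, a 1.22-fold difference, lower on 3 of 4 arrays, but at -0.079 with the local median removed and -0.16 with shared outer values left out. No single gene passed the test over all genes. On replicate 1 none of these 3 groups was lower: the shifts there were 0.28 for glycolysis, 0.08 for the ribosomal proteins and 0.08 for the translation factors.

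Among the glycolytic genes 18 had a mean below 0 and 4 a mean above it. ENO1, which encodes an enolase, had a mean of -1.69 ± 0.74 (SD, n = 4) and a ratio of -1.57 on replicate 1. GPM1, the phosphoglycerate mutase gene, had a mean of -1.89 ± 1.00. These 2 genes passed the threshold when p-values were adjusted over the list alone, and 0 genes of the list passed over all genes. ENO2, the other enolase gene, was at -1.69 ± 1.13, and the aldolase gene FBA1 was at -1.53 ± 1.54. On replicate 1 their ratios were above 0, at 1.06 for ENO2 and 1.08 for FBA1. PGK1, the phosphoglycerate kinase gene, was named after its values were seen, and its mean of -0.03 ± 2.58 had the widest spread of the list. By camera the list's shift had an adjusted p = 2.78e-05 at the preset correlation, and adjusted p = 0.356 with an estimated correlation. That estimate was -0.012, below the preset 0.01, so a higher correlation between these genes did not end the call.

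Of the ribosomal protein genes 100 had a mean below 0 and 32 a mean above it. At an unadjusted p under 0.05 there were 27 lower members and 1 higher member, and 0 members passed over all genes or adjusted over the list alone. RPP0, which encodes the stalk protein of the large subunit, was at -1.44 ± 0.45 (SD, n = 4). RPL33B was at -1.85 ± 0.99, its near-identical copy RPL33A at -1.71 ± 0.93, and RPL1B at -1.78 ± 1.01. RPS27A, picked among the genes of 1 sign on all 5 arrays, went the other way, at 1.07 ± 0.86. It was at -0.0070 with replicate 2 turned and held a value shared with neighbouring spots on 2 arrays. The list's shift had an adjusted p = 3.64e-09 by camera and adjusted p = 0.483 with an estimated correlation. Spots of copies with near-identical sequence can bind the same cDNA, so values of such pairs are not separate measurements.

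Of the translation factor genes 28 had a mean below 0 and 12 a mean above it, with 7 lower and 1 higher at an unadjusted p under 0.05. YEF3, the fungal elongation factor 3 gene, was at -1.28 ± 0.51 (SD, n = 4). SUP45, which encodes a release factor, was at -1.42 ± 0.94, and PRT1, a subunit gene of the initiation factor that recruits the small subunit, was at -1.16 ± 0.77, or -0.20 with the local median removed. The elongation factor 1A genes TEF1 and TEF2, a near-identical pair, were at -1.46 ± 1.25 and -1.90 ± 2.52. With replicate 2 turned, YEF3 was at -0.998, SUP45 at -0.060, PRT1 at -0.047, TEF1 at 0.21 and TEF2 at 0.93, while the list was at -0.32. On replicate 1 these genes were at 0.57, 0.010, -0.93, 1.40 and -0.095 in that order. The list's adjusted p by camera was 0.0462, with 0 members past the threshold over all genes or adjusted over the list alone, and adjusted p = 0.483 with an estimated correlation. The call ended without replicate 3 (adjusted p = 0.334), without replicate 4 (0.175) and without replicate 5 (0.182). Limma's fry, which tests whether a list's genes move one way on balance, gave adjusted p = 0.0971 for glycolysis, 0.264 for the ribosomal proteins and 0.129 for the translation factors.

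**Figure D1:**
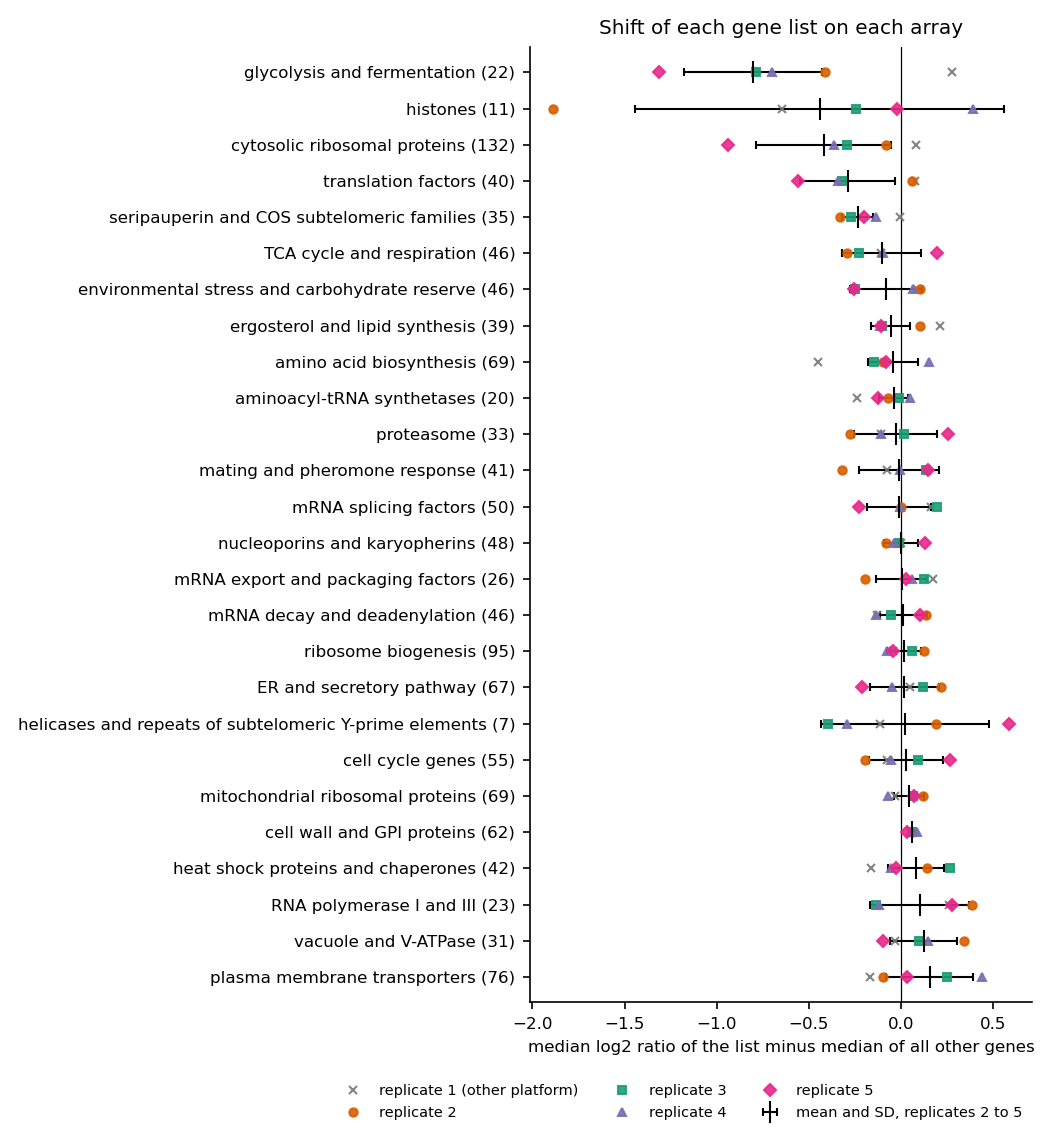
Each row is a gene list with its number of measured genes, and the horizontal axis is the median log2 ratio of the list minus the median of all other genes. Coloured points are replicates 2 to 5, grey crosses are replicate 1 on the other platform, and bars are the mean and SD of replicates 2 to 5. As deposited, glycolysis lies lowest, at -0.80, and the plasma membrane transporters highest, at 0.16; with replicate 2 turned, the histones lie highest, at 0.50 ± 0.96.

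The other 23 lists did not pass, with adjusted p from 0.0629 to 0.933. The shifts of 15 of them changed sign in at least 1 of 3 settings: 6 with the local median removed, 3 with shared outer values left out and 12 with replicate 2 turned. Genes of the export machinery itself, among them the mRNA export and packaging factors (26 genes), lay at 0.00 ± 0.14 (SD, n = 4). In that list DBP5, an RNA helicase of the pore's cytoplasmic face, was at -1.04 ± 0.62 and the helicase gene SUB2 at -0.996 ± 1.23. The cap-binding gene STO1 was at 0.90 ± 1.02 and the nuclear basket gene MLP2 at 0.43 ± 0.30. With the local median removed, DBP5 was at -0.016, SUB2 at -0.83, STO1 at 0.32 and MLP2 at 0.25. With replicate 2 turned, DBP5 was at -0.19, SUB2 at 0.010, STO1 at -0.31 and MLP2 at 0.40. The nucleoporins and karyopherins lay at 0.00 ± 0.09, the mRNA splicing factors at -0.01 ± 0.17 and the mRNA decay and deadenylation genes at 0.01 ± 0.13. YRA1 was at 0.23 ± 0.88 and MEX67 at -0.23 ± 0.78, both within the spread between arrays. On 3 of the 4 arrays MEX67 and MLP2 each have a value shared with neighbouring spots, so their means may not be their own ratios. STO1 has one on 2 arrays, and DBP5 and SUB2 on 1. The SNU66 gene of the splicing list was at -1.10 ± 0.16, but at -0.28 with the local median removed and 0.90 on replicate 1.

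The plasma membrane transporters (76 genes) lay at 0.16 ± 0.24 (SD, n = 4), with 47 members above 0 and 29 below, camera adjusted p = 0.0629 and adjusted p = 0.922 with an estimated correlation. The shift was 0.061 without replicate 4 and 0.062 with the local median removed, but 0.24 without replicate 2 (adjusted p = 0.00788) and 0.20 without replicate 5 (0.0139). The hexose transporter gene HXT15 was at 1.40 ± 0.92, the sulfate permease gene SUL2 at 1.19 ± 0.90, the arginine permease gene CAN1 at 1.18 ± 1.05 and the potassium transporter gene TRK1 at -1.48 ± 1.42. With the local median removed these 4 were at 0.91, 0.41, 0.32 and -1.31. The seripauperin and COS families, genes near chromosome ends, lay at -0.24 ± 0.08, lower on 4 of 4 arrays, with adjusted p = 0.223 by camera. That shift was -0.063 ± 0.086 with the local median removed, -0.13 with shared outer values left out and -0.069 with replicate 2 turned. Histone genes lay at -0.44 ± 1.00, with -1.89 on replicate 2 and 0.04 without it. The histone H2A genes HTA1 and HTA2 were at -3.36 and -3.48 on that array, and at 0.42 and 0.30 on replicate 4.

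Among metabolic lists, the TCA cycle and respiration genes lay at -0.11 ± 0.22 (SD, n = 4), amino acid biosynthesis at -0.04 ± 0.13, ergosterol and lipid synthesis at -0.05 ± 0.11, and environmental stress and carbohydrate reserve genes at -0.08 ± 0.19. GSY2, a glycogen synthase gene of the last list, was at -2.25 ± 1.58 and the fumarase gene FUM1 at -1.42 ± 1.16 (-2.28 and -0.67 with the local median removed). Mitochondrial ribosomal proteins lay at 0.05 ± 0.08, with RSM23 at 1.24 ± 0.44 and MRPL32 at 1.16 ± 0.71 (0.57 and 0.63 with it removed). Ribosome biogenesis genes lay at 0.02 ± 0.09, RNA polymerase I and III genes at 0.10 ± 0.27 and aminoacyl-tRNA synthetases at -0.04 ± 0.08. The polymerase list was at -0.0082 with the local median removed and -0.091 with replicate 2 turned, and the synthetases were at 0.16 ± 0.11 with the local median removed and -0.12 ± 0.12 with shared outer values left out. Heat shock proteins and chaperones lay at 0.08 ± 0.15 and the proteasome at -0.03 ± 0.22.

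The ER and secretory pathway lay at 0.02 ± 0.19 (SD, n = 4), the vacuole and V-ATPase at 0.12 ± 0.18 and the cell wall and GPI proteins at 0.06 ± 0.02. The vacuole list was at -0.0020 with shared outer values left out, and the small cell wall shift did not hold, at -0.027 ± 0.042 with the local median removed and 0.030 ± 0.065 with replicate 2 turned. Cell cycle genes lay at 0.03 ± 0.20, mating and pheromone response genes at -0.01 ± 0.22, and the helicases of the subtelomeric Y-prime elements (7 genes) at 0.02 ± 0.46. Cell cycle genes were at 0.28 ± 0.34 with shared outer values left out and 0.13 with replicate 2 turned (adjusted p = 0.0668), where mating genes were at 0.15. SRP72, a subunit gene of the signal recognition particle, was at -1.11 ± 0.21 and below 0 on all 5 arrays. STE2, the alpha-factor receptor gene, was at -1.59 ± 0.71 and also below 0 on all 5 arrays. The mating genes MSG5 and FIG2 were at -1.73 ± 0.85 and -1.13 ± 0.40, and the vacuolar sorting gene VPS41 at -2.46 ± 1.72, but on replicate 1 these 3 were at 0.72, 1.34 and 0.41, and VPS41 was at -0.018 with replicate 2 turned. Of the 104 genes picked from the lists, 53 had the opposite sign on replicate 1. PLB3, a phospholipase B gene of the cell wall list, was at -1.78 ± 0.64. For 9 of the 26 lists the difference of medians and camera's direction had opposite signs, none of them a list that passed.

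Over single genes, 0 of the 5539 genes tested passed Benjamini-Hochberg adjustment in limma, and the smallest adjusted p was 0.834. At an unadjusted p under 0.05 there were 300 genes, 79 higher and 221 lower, against a mean of 196.3 in data with genes shuffled within arrays. The median SD of a gene over the 4 arrays was 0.77 log2 units. The test recovered 43% of simulated changes of 2 log2 units and 88.4% of changes of 3, so changes of 1 log2 unit (0.9% recovered) were not detectable with this number of arrays.

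The genes with the largest means of 1 sign on all 5 arrays are named although none passed (adjusted p = 0.834 for each). On the lower side VID30, a subunit gene of the GID ubiquitin ligase, was at -2.58 ± 1.69 (SD, n = 4) and YHR131C at -2.32 ± 1.199. RBL2, a tubulin folding cofactor gene, was at -2.21 ± 1.10, the Ty retrotransposon reading frame YBL005W-B at -2.15 ± 1.60, and NAB3, which encodes an RNA-binding termination factor, at -1.99 ± 1.15. RBL2 and NAB3 lie in adjacent rows of block 30 and were at -0.49 and -0.27 once the local median was removed, where VID30 and YHR131C were at -2.80 and -2.39. With the sign of replicate 2 turned, VID30 was at -0.25, YHR131C at -0.56, RBL2 at -0.86, YBL005W-B at -0.24 and NAB3 at -0.60. The means of PAU7 (-2.10 ± 2.94), DFP2 (-1.98 ± 2.46), YCR101C (-1.91 ± 3.06) and MRX20 (-1.88 ± 2.95) rested on replicate 5. PAU7 and YCR101C held 1 shared value on that array. With the local median removed, PAU7 was at -0.26, DFP2 at -0.17, YCR101C at -0.06 and MRX20 at -0.29. The means of TEF2, RPS21B (-1.89 ± 2.12) and the polymerase II phosphatase gene FCP1 (-1.85 ± 2.37) rested on replicate 2.

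On the higher side the means were smaller. HSP78, a mitochondrial chaperone gene, was at 1.30 ± 0.64 (SD, n = 4). TFC4, a subunit gene of transcription factor IIIC, was at 1.204 ± 0.89, VHC1 at 1.19 ± 0.87, XYL2 at 1.16 ± 1.01 and the signal peptidase gene SPC3 at 1.16 ± 1.03. NPL6, a chromatin remodelling gene, was at 1.13 ± 0.70, the clathrin adaptor gene GGA1 at 1.07 ± 0.45, the kinase gene YAK1 at 1.05 ± 1.04 and MLF3 at 1.02 ± 0.72, beside SUL2, MRPL32 and RPS27A. With the local median removed, HSP78 was at 0.66 and GGA1 at 0.33. The spots of TFC4, XYL2, SPC3, NPL6 and MLF3 start in columns 17 to 19 of block 3. Each of these genes shares a value with neighbouring spots on 2 or 3 of the 4 arrays. With the local median removed they were at 0.35, 0.14, 0.19, 0.43 and 0.48, so they may not be separate results. Among the other higher genes, VHC1 held a shared value on 4 of the 4 arrays, and SUL2 and YAK1 on 3. HSP78, MRPL32 and RPS27A held one on 2 arrays and GGA1 on 0. VHC1 was at 0.38 and YAK1 at 0.37 with the local median removed. The order depends on the sign of replicate 2: with it turned, MRPL32 was at 1.06, HSP78 at 0.98, GGA1 at 0.82, XYL2 at 0.28, SPC3 at 0.15, VHC1 at 0.12 and RPS27A at -0.0070. Of the 126 genes picked by the naming rule, the means of 83 shrank by more than 1.5 times or changed sign with the local median removed. Those of 94 did so with replicate 2 turned, a change that shrinks the mean of any gene with 1 sign on all 4 arrays. Most of these genes were picked for large means or small p-values in the main setting, which favours smaller means in any other. The 83 is thus not a measure of position effects.

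**Figure D2:**
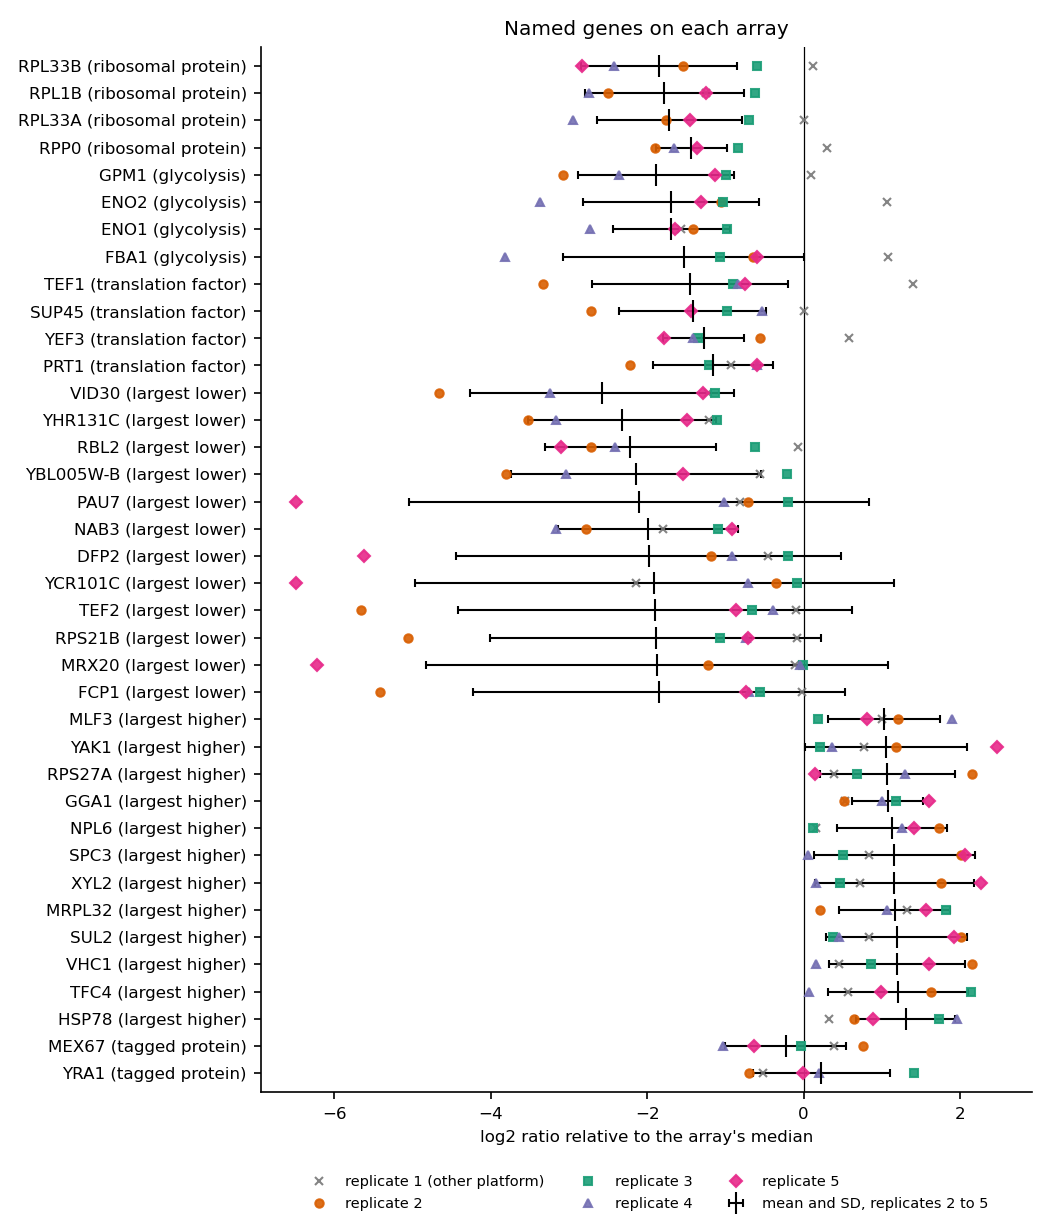
Each row is a named gene with the group it was named for, and the horizontal axis is its log2 ratio relative to the array's median. Points are single arrays, and bars are the mean and SD of replicates 2 to 5. The ENO1 points lie below 0 on every array, while the PAU7 mean rests on the replicate 5 value of -6.48, which is shared with YCR101C.

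The arrays agreed within themselves far more than with one another. Duplicate spots of a gene on an array correlated with Pearson r from 0.76 to 0.89, and from 0.61 to 0.74 once the local median was removed. Between the 4 arrays r across genes ran from -0.03 to 0.13, and with replicate 1 included from -0.06 to 0.13. Adjacent spots of different genes correlated with r from 0.42 to 0.65, and from 0.09 to 0.22 once the local median was removed, while r between arrays then ran from 0.04 to 0.14. These correlations are across spots or genes, which are not independent replicates. Values so near 0 do not show whether the arrays run the same way, and the deposited median of replicate 2, at 1.96, had the opposite sign to those of replicates 3 to 5. The labels give 1 orientation for every array, so replicate 2 was kept as deposited, but means that rest on it carry this doubt. With its sign turned, GPM1 was at -0.35 and ENO1 at -0.98. Replicates 3 and 5, which share a session code, correlated with r = 0.03.

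The 2 copies of ribosomal protein genes followed each other within an array on replicates 1 to 4. Spots of near-identical copies can bind the same cDNA, so this does not show that the 2 transcripts were recovered alike. Across 54 pairs on the platform of 4 arrays and 56 on the other, Pearson r was 0.42 on replicate 1, 0.57 on replicate 2, 0.68 on replicate 3, 0.64 on replicate 4 and 0.22 on replicate 5. Permutation tests adjusted over the 5 arrays gave p = 0.0014 on replicate 1, 1.7e-05 on replicates 2, 3 and 4, where the raw 1e-05 is the smallest that 100000 permutations can give, and 0.1 on replicate 5. Of the 5539 genes, 789 had 1 sign on all 4 arrays, or 14.2% against 12.5% by chance. On all 5 arrays it was 366 genes, or 6.61% against 6.25%. The mean of the 4 arrays and replicate 1 correlated with r = -0.02 across genes.

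**Figure D3:**
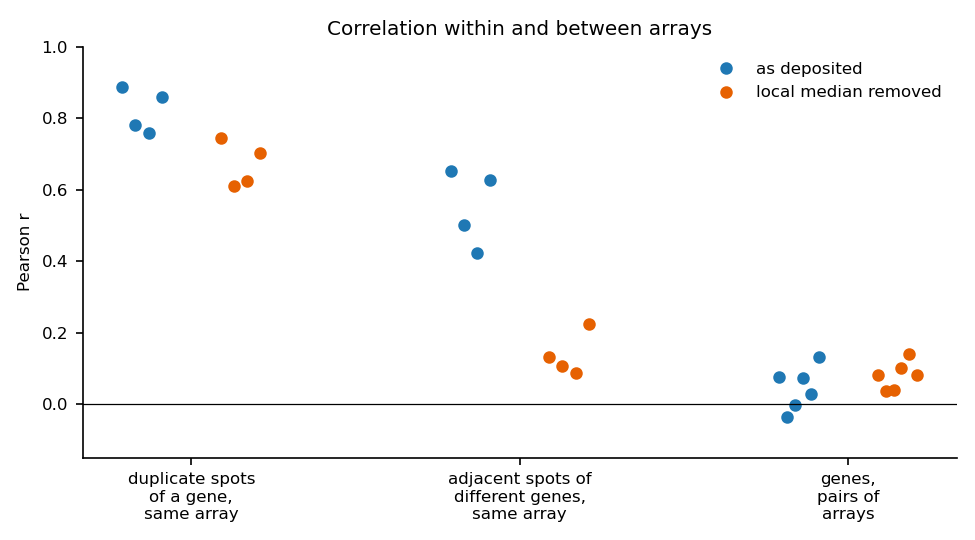
Pearson r for duplicate spots of a gene, for adjacent spots of different genes and for genes between pairs of arrays, for replicates 2 to 5. Each point is an array or a pair of arrays, in blue as deposited and in orange with the local median removed. The r of duplicate spots is at least 0.76 as deposited, and r between pairs of arrays is at most 0.13.

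No relation between the length of a gene and its ratio was detected. Spearman rho between gene length, which may include introns, and log2 ratio across genes was 0.0022 ± 0.0247 (SD, n = 5). The exact two-sided sign-flip p was 0.9375, where 5 arrays allow no p under 0.063. The sign of so small a mean turned when the ribosomal protein genes were left out (-0.0061).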

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

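Of 156 values compared over the arrays, 14 had 1 array far from the others by Dixon's criterion, where chance gives about 1 in 20 and so 7.8. Replicate 2 was the outlying array in 7 cases, replicate 5 in 4, replicate 4 in 2 and replicate 3 in 1. Most of the genes compared were picked for large means or small p-values, which favours extreme values.

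On replicate 2, TEF2 was at -5.66 while the other arrays of its platform lay between -0.87 and -0.39. TEF1, its near-identical copy, was at -3.33 against -0.91 to -0.75. On the same array FCP1 was at -5.41 against -0.74 to -0.55 and RPS21B at -5.06 against -1.07 to -0.71. STO1, a cap-binding gene, was at 2.42 against 0.29 to 0.58. The splicing gene SNU114 was at -0.047 against 0.92 to 0.98. The ergosterol and lipid synthesis list had a shift of 0.10 against -0.11 to -0.10.

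On replicate 5, PAU7 and YCR101C both had the value -6.48, against -1.02 to -0.20 and -0.71 to -0.08 on the other arrays. The spots of these genes start in the same column of block 23, in rows 1 and 3. PAU7 shares a value with neighbouring spots on 2 arrays and YCR101C on 1. The equal values on replicate 5 are then 1 shared value and not separate ratios of these genes. TRK1 was at -3.59 against -1.06 to -0.62. The subtelomeric helicase gene YRF1-4 was at 0.58 against -0.87 to -0.83.

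On replicate 4 the glycolytic genes ENO2 and FBA1 were at -3.37 and -3.82, against -1.31 to -1.03 and -1.06 to -0.59. On replicate 3 MOT2, a gene of the deadenylation complex, was at 1.83 against 0.54 to 0.75.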

How the results depend on the processing

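The settings that removed the local median, left out outer spots with a shared value, turned replicate 2 or set a session block were chosen after seeing the data. No gene passed under any of the 19 alternatives run for genes, including limma without moderation and robust eBayes. At an unadjusted p under 0.05 there were 198 genes when treat tested against a fold of 1.2, and 231 to 340 when each array was left out. Without centring the split was 0 higher to 203 lower in place of 79 to 221, since the median of all gene means was then -0.99. With an estimated correlation 0 lists passed: glycolysis stayed at -0.80 (adjusted p = 0.356), the ribosomal proteins at -0.42 (0.483) and translation factors at -0.29 (0.483). Removing the local median as well also left 0 lists, at -0.56 (0.315), -0.30 (0.532) and -0.079 (0.532). Without that removal the estimated correlation was -0.012 for glycolysis, 0.072 for the ribosomal proteins and -0.0032 for translation factors, against the preset 0.01. For glycolysis and translation factors a higher correlation between genes therefore did not end the call. Under all other alternatives run for lists the glycolysis and ribosomal protein lists stayed past the threshold and lower, at -0.93 to -0.63 and -0.53 to -0.25 when each array was left out, when 2 to 4 lists passed. The translation factor call was lost without centring (-0.29, adjusted p = 0.0508), with the same-session arrays averaged (-0.26, 0.170), with the other platform's array added (-0.22, 0.0701), with shared outer values left out (-0.16, 0.550), with the rank version of camera (-0.29, 0.0846), and without replicate 3, 4 or 5 (range over all 4 arrays left out, -0.41 to -0.20). The cause was not tested. The transporter list passed under some alternatives, with adjusted p from 0.00788 to 0.922. Gene length had rho -0.0061 without the ribosomal protein genes. When each array was left out, rho ran from -0.0030 to 0.0114 and was below 0 without replicate 4 (-0.0029) or 5. Of 414 values of the other lists 58 had the opposite sign to the main value, as did 50 of 2374 values of named genes. Requiring values on all 4 arrays removed no gene and tests nothing. A session block by duplicateCorrelation could not be fitted to 3 sessions, and with its correlation set to r = 0.028 there were 0 genes. Robust eBayes and a session block do not enter camera and were not run for lists, and GC content and introns were not run. No paired analysis was possible because the arrays form 1 group. Signal over background was not used here, so its limit on precision is unknown.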

Other observations

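The gene with the smallest p was AVO1, which encodes a subunit of the TORC2 kinase complex, at -2.20 ± 0.67 (SD, n = 4) and 4.58-fold from the array median, with adjusted p = 0.834 in limma and a ratio of 0.05 on replicate 1. SPT8, a gene of the SAGA coactivator, was at -2.20 ± 1.28, and MDY2, which acts in the insertion of tail-anchored proteins, at -2.05 ± 1.16. REE1 was the only gene above 0 among the 8 of smallest p, at 1.59 ± 0.48. With the local median removed AVO1 was at -2.38 and SPT8 at -1.61, while MDY2 was at -0.21 and REE1 at 0.63. These genes were chosen after their values were seen.

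The tests on shared local values, slide position, gene assignment and spot noise below were chosen only after the results were seen. Outer spots of ribosomal protein genes kept their own value more often than those of other genes: 62.6% against 40.7% on replicate 2, 94.7% against 81.8% on replicate 3, 77.9% against 67.7% on replicate 4 and 70.2% against 21.5% on replicate 5. Of the 26 lists, 11 did so on all 4 arrays, the transporters and the seripauperin and COS families among them. A candidate explanation for the 3 lower lists is that many other spots carry local values in place of their own. Over outer spots with their own value, glycolysis lay at -0.57 ± 0.12, and at -0.97 ± 0.23 with shared outer values left out, which argues against this as the whole cause there. Translation factors leave it open, at -0.53 ± 0.09 but -0.16 ± 0.26 with those left out (adjusted p = 0.550 by camera). Ribosomal proteins also leave it open, at -0.36 ± 0.62, and -0.50 ± 0.38 with those left out (adjusted p = 3.39e-11 by camera at the preset correlation). Over all outer spots the median of own values minus that of shared values was -1.59, -0.35, 0.30 and -0.66 on replicates 2 to 5. With the local median removed, glycolysis was at -0.56 ± 0.41 and past the threshold at the preset correlation, with adjusted p = 0.315 with an estimated correlation, which argues against position on the slide as the whole cause. Ribosomal proteins at -0.30 ± 0.38 and translation factors at -0.079 ± 0.096 also passed by camera at the preset correlation (adjusted p = 9.42e-10 and 0.0394). With an estimated correlation both had adjusted p = 0.532. Both shifts lay within their spread, which leaves position open for these 2 lists. Unequal recovery in the precipitates and a dye effect on these genes stay open and untested, since no array with turned dyes is known. Every array sets 1 precipitate against the other and none holds input RNA. Unequal recovery can then not be told apart from unequal RNA levels before precipitation. The ratios were not examined against spot intensity, as only ratios were used here.

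The 4 arrays allow 8 patterns of turned signs, too few for a share under 0.05. For lists, 2 of the 8 gave at least 3 lists, and the highest other pattern also gave 3. For genes at an unadjusted p under 0.05, 2 of the 8 gave at least the real 300, and the highest other gave 310. In both cases the other pattern was the one with replicate 2 turned, whose median has the opposite sign to the other 3.

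The arrays hardly correlated with one another. Values shared between spots are unlikely to be the whole cause, since over outer spots with their own value on both arrays the highest r was 0.179, and position on the slide is unlikely too, as r reached only 0.141 with the local median removed. Spots matched to the wrong genes on a whole array would end the excess of own values at ribosomal protein genes. That excess was at least 10.2 percentage points on each of the 4 arrays. The check covers outer spots only and cannot exclude a mismatch of part of the spots. Pairs of ribosomal protein copies correlated with r = 0.57, 0.68 and 0.64 on replicates 2, 3 and 4, but with 0.22 on replicate 5. Noise of single spots is unlikely as the whole cause, since over inner spots with the local median removed r of duplicate spots exceeded r of adjacent spots of different genes by at least 0.457 on each array (mean 0.538 ± 0.0966, SD, n = 4), against r of at most 0.131 between arrays. Noise from steps before hybridisation, which both spots of a gene share, and a true difference between the precipitations were not tested.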
